A study of Mus musculus with 54 samples.

How the data were processed

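The series holds 54 single cells from mouse lung, all labelled as interstitial macrophages, the macrophages of the lung tissue between the airspaces. Per the labels' protocols, each cell was made into a full-length cDNA library by a modified SMART-seq2 protocol with tagmentation by a Nextera kit, and the libraries were sequenced as paired ends on an Illumina HiSeq 2000. The labels name no animal, sort gate, plate or batch. The cells therefore count as 1 sample of 1 group, and cells are not replicates. No p-value or standard error was made from them, and no pairing of samples exists. Counts of genes that differ between clusters describe these cells and rest on no test.

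The values the authors deposited are TPM, RSEM's measure of transcript abundance scaled to a fixed total, 1 table per cell with 43280 gene symbols. RSEM is named in the submitters' processing notes without a version. The aligner, genome build and annotation were not given in the sources used here, so no coordinates are printed. The totals of the deposited TPM values ran from 997509 to 1e+06 per cell. TPM keeps no sequencing depth, so the depth of each cell is unknown, and the number of genes above 0 stood in as the only per-cell measure of library complexity. In all, 14890 symbols were above 0 in at least 1 cell. Of the symbols in the tables, 39469 matched a current mouse gene name, and 2 list genes were found under the older symbols Emr1 (Adgre1) and Sepp1 (Selenop), taken from a RefSeq table of assembly GRCm38.p6 that was used for names alone.

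Levels were taken as log2(TPM + 1), so differences between means on this scale understate the change of low genes. Cells with at least 1000 genes above 0 were kept, which all 54 were. For clustering, genes above 0 in at least 5 cells were ranked by the variance above a lowess trend on the mean (fraction 0.3), and the first 1000 were used. Mitochondrial and ribosomal protein genes were left out, and so were the 31 genes of the Lyve1 programme, MHC class II and MHC class II-high partner lists. Genes were scaled to unit variance, reduced to 10 principal components and joined by Ward linkage into 2 clusters, the number of populations in the title of the series. The clustering was repeated on each of a pair of disjoint gene sets, the odd and the even genes in alphabetical order, and the splits were compared by the adjusted Rand index, which is 1 for identical splits and near 0 for unrelated ones. The same index was computed on 100 data sets in which each gene was shuffled across cells. No doublet caller was run, since the tables hold no molecule counts; cells with at least 3 markers above 10 TPM of another cell type were listed instead.

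A list level is the mean log2(TPM + 1) of its genes, and a list score is the mean of their scaled values. Each list difference between clusters, and each Spearman's rho, was placed as a percentile among 10000 random lists whose genes came from the 100 nearest in mean level. These percentiles describe this set of cells and are not tests. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 carries the limit given by 3 counts of the total. Both cover counting error only. Detection was a value above 0, with 1 and 10 TPM as alternatives.

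The gene lists, and the rules that picked further genes from the data, were set before the data were examined. The 21 lists have 192 members. The rules picked the 12 genes with the highest and the 12 with the lowest rho with a contrast score (MHC class II score minus Lyve1 programme score). Those came from genes above 0 in at least 10 cells, outside the lists left out of the clustering and the ribosomal protein and mitochondrial genes. The rules also picked the 10 genes with the largest difference in each direction between clusters, and the 10 genes with the highest mean level. For the cluster differences each gene was measured in the clusters made from the gene set that did not hold it, among genes above 0 in at least 20% of the cells of the cluster with the higher level. Part of the B cell list is not reported here. A few other genes, named as such, were chosen after their values were seen.

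The clustering and list steps were tested on simulated data, made by shuffling every gene across the cells, with 10 data sets for each setting. When 200 genes were multiplied by 4 or 16 in 20 cells, the clustering did not find the groups (median adjusted Rand index with the planted groups -0.016 and 0.080), and at 64-fold it did (median index 1), while the index between the disjoint gene sets was 0.173 and 8.50% of the planted genes ranked among the first 200, against 5.25% with nothing planted. A further setting was then added, in which the highest values of 200 genes were placed in 20 cells. There the median adjusted Rand index with the planted groups was 0.854, that between the disjoint gene sets was 0.654, and 79.2% of the planted genes ranked among the first 200 of 5291. The gene ranking thus recovered the planted genes only in this last setting, where they were mostly on in some cells and low or off in others, and not at any fold tried. Measured between the planted groups, a planted list of 8 genes had a median percentile of 98.5 at 4-fold and 100 at 16-fold, against 54.7 with nothing planted. With nothing planted, the index between gene sets ran from -0.095 to 0.056.

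The alternatives tried were other cell filters, detection thresholds, pseudocounts of 0.1 and 10, scaling by the median of ratios, a filter on rarely detected genes, other correlation measures, and other clustering settings. A further 8 alternatives were added after the data were seen. A share was taken to have moved when it left the 95% interval of the reported one, and another value when it differed from the reported one by more than 1.5 times. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.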

Results

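The data are TPM values of 54 single lung cells labelled as interstitial macrophages. Between 1227 and 4946 genes were above 0 per cell, with a median of 2802.5 (quartiles 2452 and 3203). The genes with the highest mean levels were Lyz2, Ftl1, Apoe, Dusp1, Actb, Fth1, mt-Nd1, C1qb, mt-Cytb and mt-Atp8. Lyz2, which encodes lysozyme, had a median of 44585 TPM. Mitochondrial genes made up a median of 3.49% of the TPM. There are no biological replicates, so the values below describe these cells alone.

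Most genes of the macrophage identity list were present in most cells. The lowest list levels were 2.99 in cell 40, 4.48 in cell 36 and 5.14 in cell 29, and the highest was 10.3. C1qa, C1qb and C1qc, the genes of complement component C1q, were at 10 TPM or more in 51, 52 and 51 of the 54 cells. Csf1r, the receptor for the macrophage growth factor CSF1, reached that level in 49 cells, Cd68 in 47 and Emr1 (Adgre1, the gene of F4/80) in 44. Mertk, an engulfment receptor, and Fcgr1, a receptor for IgG, did so in 12 and 8 cells.

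Values above 0 fell into a low and a high range, with the fewest between them near 10 TPM. In the median cell 40.5% of the values above 0 were under 10 TPM, so detection above 0 and presence at 10 TPM or more are given side by side. Cell 31 differed, with 0.075% of its values in the low range and a lowest value of 9.50 TPM.

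**Figure D1:**
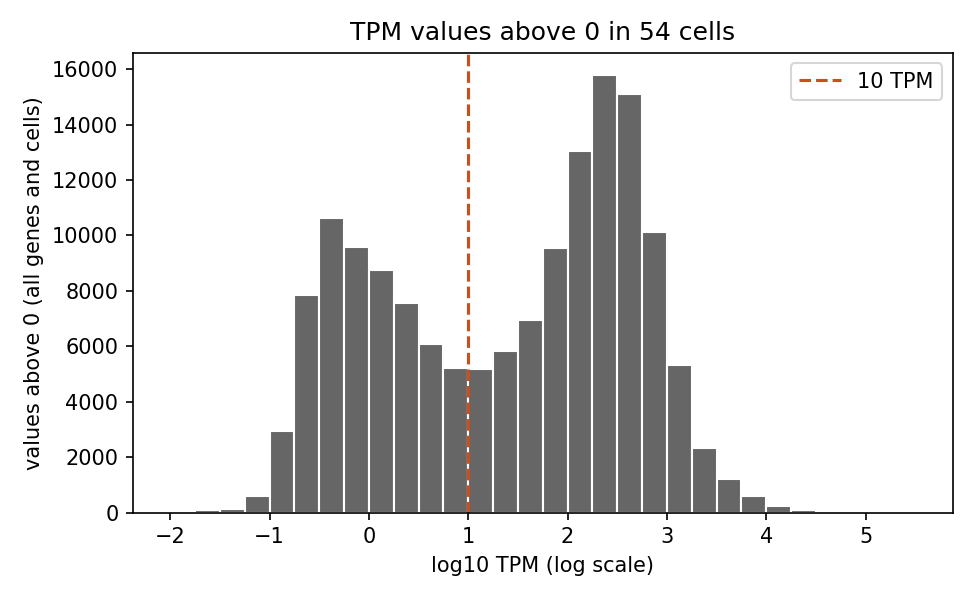
All TPM values above 0, over every gene and the 54 cells, in bins of equal width on a log10 axis; the dashed line marks 10 TPM. The bars form a low and a high peak, and the bins on either side of the line hold 5232 and 5164 values.

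The title of the series names a pair of interstitial macrophage populations, known from the study as Lyve1-high MHC class II-low and Lyve1-low MHC class II-high. Lyve1, which encodes a hyaluronan receptor, was above 0 in 11 of 54 cells, or 20.4% (95% interval 10.6 to 33.5%), and at 10 TPM or more in 8 cells, or 14.8% (6.62 to 27.1%). H2-Ab1, which encodes the beta chain of the MHC class II molecule I-A, was above 0 in 49 cells, or 90.7% (79.7 to 96.9%). It was at 10 TPM or more in 29 cells, or 53.7% (39.6 to 67.4%), so the threshold changes this share beyond its counting error. At 10 TPM, 6 cells had both genes, 2 had Lyve1 without H2-Ab1, 23 had H2-Ab1 without Lyve1 and 23 had neither. Folr2, a folate receptor gene, Cd163, a haemoglobin scavenger receptor gene, and Mrc1, the mannose receptor gene, reached 10 TPM in 11, 12 and 25 cells, of which 8, 10 and 19 also had H2-Ab1. These overlaps carry a cluster difference. In cluster 1, described below, Folr2, Cd163 and Mrc1 reached 10 TPM in 10, 11 and 24 cells. Of those, 7, 9 and 18 had H2-Ab1, as did 24 of all 33 cells of that cluster.

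Lyve1 alone did not run opposite to the MHC class II genes over these cells. Most cells held none of it, so its rho can show little. Across all 54 cells rho between Lyve1 and the mean level of the 8 MHC class II genes was 0.172 (Pearson's r 0.183), at percentile 70.9 of random pairs, and r was 0.087 without the 2 cells farthest from the median. The cells fall into 2 clusters, described next, and within them rho was 0.017 (33 cells, r 0.039) and 0.025 (21 cells, r 0.516). The r in the 21 cells rests on the 2 of them with Lyve1, without which it cannot be computed. Among the cells with Lyve1 above 0 alone, rho was -0.127. Scores of the whole lists gave a rho of -0.161 (r -0.055), lower than every random pair of lists (percentile 0, random median 0.379), and r was -0.093 without the 2 farthest cells. Within the clusters rho of the scores was -0.182 (r -0.170) in the 33 cells and -0.031 (r 0.447) in the 21 cells. The latter r was 0.115 without 2 cells and so rests on them. These were 2 relations computed in 1 family.

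**Figure D2:**
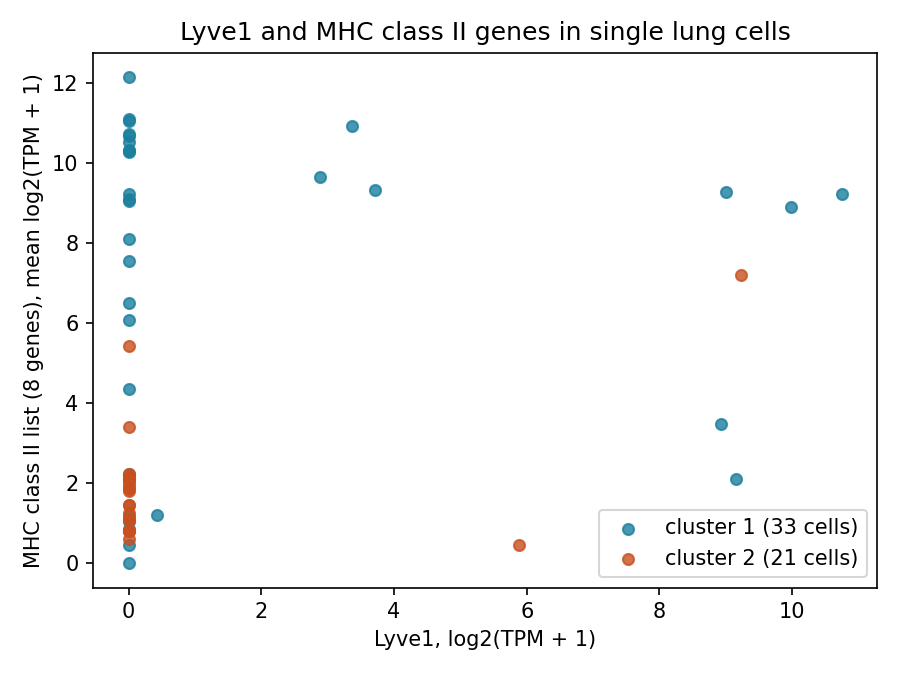
Each point is 1 cell, with Lyve1 as log2(TPM + 1) on the x axis and the mean log2(TPM + 1) of the 8 MHC class II genes on the y axis, coloured by cluster. Most cells lie at 0 on the x axis, and the 8 cells with Lyve1 at 10 TPM or more include cells with high and with low MHC class II levels.

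The cells were split into 2 clusters, the number of populations in the title; the split does not test that number. Cluster 1 held 33 cells and cluster 2 held 21. Splits from disjoint gene sets put 51 of the 54 cells on the same side, an adjusted Rand index of 0.786, against a median of -0.013 and a highest value of 0.151 in 100 shuffled data sets, which keep no shared gradient, such as one in library complexity. Cells 8, 12 and 13 changed sides. Cluster 2 cells had more genes above 0, with medians of 2983 against 2625, and more at 10 TPM or more, 2100 against 1395. With the number of genes detected taken out, the index was 0.540, and 47 of the 54 cells kept their side. Cluster 2 also had higher levels of 10 markers of serous cavity macrophages (difference 2.95, given with the other observations), so the differences below are not shown to lie among interstitial macrophages.

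The MHC class II genes were lower in cluster 2. Their median level was 9.06 in cluster 1 and 1.81 in cluster 2, a difference (cluster 2 minus cluster 1) of -7.25 on the log2 scale, lower than every random list (percentile 0, random median 1.26). The genes of this list were not used to make the clusters. Cd74, the invariant chain, had a median of 22251 TPM in cluster 1 and 3.80 TPM in cluster 2. H2-Ab1 reached 10 TPM in 24 of 33 cells of cluster 1, or 72.7% (95% interval 54.5 to 86.7%), and in 5 of 21 cells of cluster 2, or 23.8% (8.22 to 47.2%). Of the 8 genes, 7 were lower in cluster 2 by more than 1 in mean log2 level, all but Ciita, the class II transactivator, which reached 10 TPM in 3 cells, all of them in cluster 1.

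The 5 genes of the MHC class II-high partner list went the same way, with a median level of 2.11 in cluster 1 and 0.05 in cluster 2 (difference -2.06, percentile 0). The chemokine receptors Ccr2 and Cx3cr1 reached 10 TPM in 13 and 11 of 33 cells of cluster 1 and in 0 of 21 cells of cluster 2, which allows a share of up to 14.3%. Cd72, Itgax and Il1b did so in 8, 4 and 3 cells of cluster 1 and in 0 of cluster 2.

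The Lyve1 programme did not move as a unit between the clusters. Its median level was 2.88 in cluster 1 and 3.33 in cluster 2, a difference of 0.45 at percentile 11.7. Of its 18 genes, 9 were lower in cluster 2 by more than 1 in mean log2 level and 5 were higher. Mrc1 (difference -6.04), F13a1 (-3.84), Stab1 (-3.67), Cbr2 (-3.62) and Folr2 (-3.06) were among the lower genes. The higher ones were Fcna (6.81), Timd4 (5.74), Ltc4s (5.12), Pf4 (4.14) and Ccl24 (3.78). Cluster 2 carried markers of serous cavity macrophages, so these opposite directions are not shown to lie among interstitial macrophages. Timd4, a receptor for phosphatidylserine, reached 10 TPM in 20 of 21 cells of cluster 2, or 95.2% (76.2 to 99.9%), and in 8 of 33 cells of cluster 1, or 24.2% (11.1 to 42.3%). Lyve1 itself reached it in 6 cells of cluster 1 and 2 of cluster 2. Inside cluster 1 the programme varied, with median levels of 4.53 and 1.99 in the 18-cell and 15-cell parts of a 3-cluster split. All its genes but Fcna and Ltc4s had the higher mean log2 level in the 18-cell part, which also had more genes above 0. With the 5 genes higher in cluster 2 left out of the list, rho between the list scores turned from -0.161 to 0.303. That choice was made after the data were seen and on the cluster difference itself. Random pairs matched to the full lists had a median rho of 0.379 (5th to 95th percentile 0.142 to 0.579), a range that holds 0.303.

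**Figure D3:**
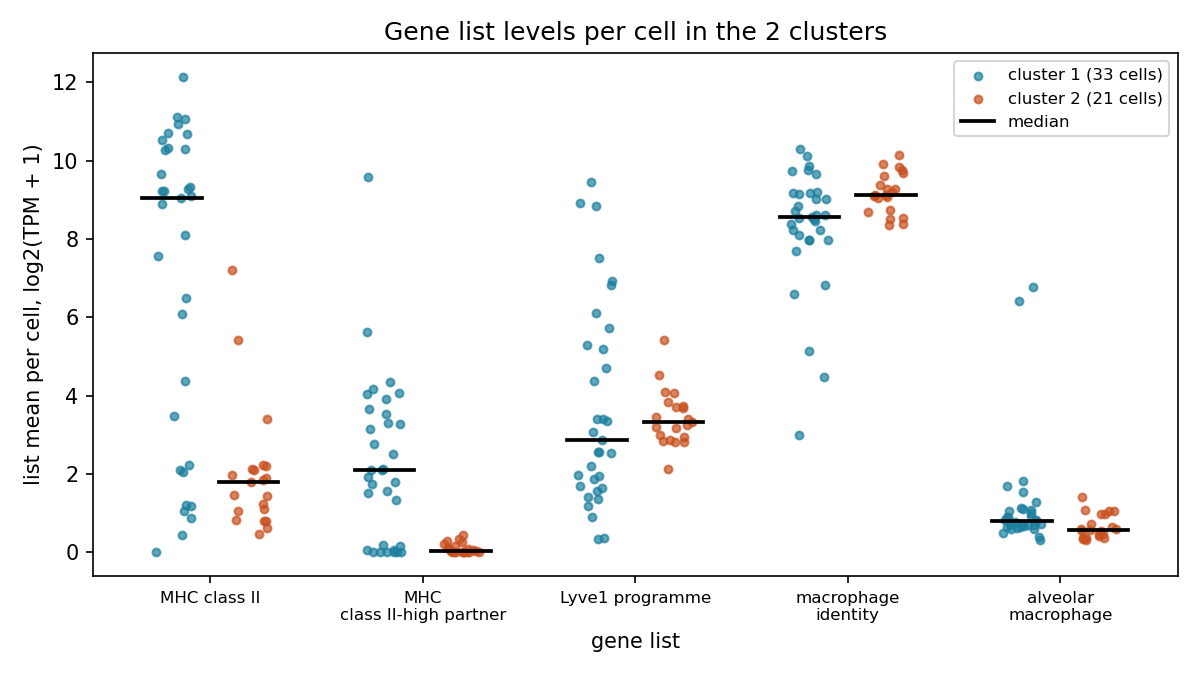
Each point is 1 cell and its mean log2(TPM + 1) over the genes of a list, for 5 lists on the x axis, with cluster 1 left and cluster 2 right in each pair and black lines at the medians. The MHC class II list has medians of 9.06 and 1.81 with overlapping cells, and the Lyve1 programme medians are 2.88 and 3.33.

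Among all genes, each measured in clusters made from the other gene set, the largest differences in favour of cluster 2 were for Prg4, Alox15, Fn1, Lrg1, Cd5l, Icam2, Padi4, Ecm1, Serpinb2 and Mcemp1, between 8.33 and 10.13 on the log2 scale. Prg4 encodes lubricin, Alox15 a lipoxygenase and Fn1 fibronectin. Alox15 had a median of 3918 TPM in cluster 2 and 0.55 TPM in cluster 1, and Fn1 of 6318 and 2.07 TPM. The largest differences in favour of cluster 1 were for Cd74 (-8.86), H2-Ab1 (-8.67), H2-Eb1 (-7.79), Cd83 (-7.44), H2-Aa (-7.07), Anxa5 (-7.01), Mrc1 (-6.52), Ighm (-6.49), Fcrls (-6.47) and Ms4a7 (-6.15). Of the identity genes, measured the same way, Itgam, the gene of CD11b, and Emr1 were higher in cluster 2 by 4.80 and 3.69, and Csf1r was lower (-1.20). The identity list as a whole had medians of 8.56 and 9.13 (percentile 25.7). Lyz2 had a median of 147630 TPM in cluster 2 and 26243 TPM in cluster 1.

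Outside the Lyve1 programme, MHC class II and partner lists and the ribosomal protein and mitochondrial genes, those that followed the contrast score most closely were Ctss, Tmem123, Slamf7, Gm4767, Gm10778, Srp68, Clec4a2, Ptp4a2, Cd52, Axl, Tmsb4x and Cd83 at its MHC class II end, with rho from 0.42 to 0.49. Ctss encodes cathepsin S, the protease that trims the invariant chain. At the other end were Ctsd, Ednrb, Ly6e, Gm16344, Cd38, Emc10, Colec12, Trf, Nutf2-ps1, Srp72, Cd36 and Emp3, with rho from -0.64 to -0.47. These rho values run over both clusters together and so carry the cluster difference: all 12 genes at this end were higher in cluster 2, by 0.62 to 6.81 in mean log2 level, and 10 of the 12 at the MHC class II end were lower there. Ctsd, which encodes cathepsin D, had medians of 518 TPM in cluster 1 and 3717 TPM in cluster 2. Gm4767 and Gm10778 reached 10 TPM in 2 cells each. Gm4767, Gm10778, Gm16344 and Nutf2-ps1 are uncertain, since reads can be split between near-identical copies.

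At least 1 marker of another cell type was above 10 TPM in 12 cells for the alveolar macrophage list, 13 for the monocyte list and 13 for the neutrophil list. At least 3 alveolar macrophage markers were above 10 TPM in 2 cells, cell 31 with 7 of 10 and cell 40 with 6. Cell 36 had 4 monocyte and 3 T or NK cell markers. The alveolar list had median levels of 0.81 in cluster 1 and 0.58 in cluster 2 (difference -0.24, percentile 3.44). The monocyte, dendritic cell, T or NK cell and epithelial lists had medians of 0.00 in both clusters, and the neutrophil list 0.16 and 0.29. Hp and Csf3r, of the monocyte and neutrophil lists, reached 10 TPM in 8 and 6 of the 21 cells of cluster 2 and in 1 and 2 of the 33 of cluster 1. Endothelial genes stood at 0.20 and 0.13, with Egfl7 alone reaching 10 TPM, in 1 cell. No mast cell or basophil, fibroblast or erythroid gene reached 10 TPM in any of the 54 cells, which allows a share of up to 5.56% for each. Of the B cell list, Ighm, the gene of the IgM heavy chain, reached 10 TPM in 22 cells, all in cluster 1, and Cd79a, Cd79b and Ms4a1 in none.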

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

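The agreement of the splits from disjoint gene sets stayed within 1.5 times of 0.786 under the 13 alternatives whose outcome was not fixed by their construction, and the MHC class II difference between clusters within 1.5 times of -7.25 under 16. Not counted here or below is the absence of a cell filter, which removes no cell, and for the agreement the removal of cells 8, 12 and 13, on which the splits differed, and for the difference the clustering with the list genes kept. The lowest agreement, 0.540, came with the number of genes detected taken out. The alternatives that use 1 cluster alone, leave out cell 31 or cells 8, 12 and 13, leave out the list genes higher in the smaller cluster, set values under 10 TPM to 0 or leave out Lyz2 were chosen after seeing the data. The share of cells with Lyve1 stayed within its 95% interval under 7 alternatives and was 9.52% in the smaller cluster alone, which holds 21 cells. The share with H2-Ab1 was 53.7% at 10 TPM or more, since that threshold leaves out the low values. The correlation between Lyve1 and MHC class II kept its sign and stayed within 1.5 times under 13 alternatives, Pearson's r and a partial rho among them. It was 0.017 in the larger and 0.025 in the smaller cluster alone, and -0.127 in cells with Lyve1 above 0. The correlation between the list scores did so under 13 as well. It was -0.055 as Pearson's r and 0.068 in the smaller cluster alone with genes rescaled there. Without the 5 list genes higher in the smaller cluster it was 0.303, and -0.042 in the larger cluster alone. The 5 genes were chosen on the cluster difference itself; otherwise the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown in TPM, so a gene listed at 0 in a cell is not shown to be absent from it.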

Other observations

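Other gene groups differed between the clusters gene by gene. Their list medians lay close together, while matched random lists were mostly higher in cluster 2, so close medians can hold a low percentile. Il6, a cytokine of inflammation, and Cxcl1, a neutrophil chemokine, reached 10 TPM in 7 and 3 cells, all in cluster 2. Ccl2, Ccl8 and Ccl12, ligands that draw monocytes, did so in 13, 5 and 6 cells of cluster 1 and in 1, 0 and 0 of cluster 2. The cytokine and chemokine list had medians of 1.54 and 1.76 (percentile 14.2). Of the proliferation list (medians 0.16 and 0.18, percentile 15.8), Mki67, Cdk1 and Birc5 reached 10 TPM in 3 cells each, all in cluster 2, whereas Pcna did so in 5 cells of cluster 1 and 6 of cluster 2, Mcm5 in 2 and 4, Top2a in 2 and 3, Stmn1 in 1 and 5 and Ccnb1 in 1 and 3. The transcription factors Irf8 and Maf reached it in 13 and 14 cells of cluster 1 and 2 and 2 of cluster 2, and Id2 in 15 and 19 (list medians 3.03 and 2.82, percentile 2.19, random median difference 1.07).

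The 14 immediate-early and stress genes differed in how many cells held them. Dusp1, Fos and Zfp36 reached 10 TPM in 53, 51 and 51 of 54 cells, Nr4a1, Fosb and Ier3 in 28, 26 and 20, and Hspa1b in 5, with list medians of 6.59 and 6.67 (percentile 2.12, random median difference 1.09) and a range of 0.81 to 9.24 over cells. Lysosomal genes had list medians of 6.68 and 6.62 (percentile 2.98, random median difference 0.95). Of these 13 genes 8 were higher in cluster 2 in mean log2 level, such as Ctsd (4.32), Lamp2 (1.70) and Ctsz (1.65), and 5 were lower, such as Cd63 (-4.03) and Axl (-2.69). Interferon response genes were low (medians 0.26 and 0.15, percentile 11.2). A split into 3 clusters kept the 21 cells of cluster 2 and divided cluster 1 into 18 and 15 cells. Their median MHC class II levels were 9.30 and 8.11, Lyve1 programme levels 4.53 and 1.99, and genes above 0 2886.5 and 2255. Identity levels were 9.03 and 8.23. The 15-cell part held cells 31, 36 and 40, which carry markers of other cell types, and cells 12 and 13, which changed sides.

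Of the tests below, those on the genes detected and on the B cell genes were chosen after the results they bear on were seen. The marker list of the test that follows was written before its values were looked at, though after the cluster genes had pointed to it. The genes of cluster 2 include several known from macrophages of the serous cavities, such as the pleural space around the lung, and a hypothesis is that such cells are among those collected; the labels name no sort that would remove them. A list of 10 further markers of those macrophages (F10, Nt5e, Thbd, Wnt2, Xdh, Car6, Vmn2r26, Cav1, Apoc1 and Hdc) was higher in cluster 2 by 2.95 in median level, above every random list, with all 10 genes in a larger share of its cells, while 5 of the 10 also reached 10 TPM in some cell of cluster 1 and 1 had been used in the clustering. The difference met the bound set in advance for the hypothesis, the 95th percentile of random lists (1.14). It does not tell such cells from interstitial cells that hold the same programme. Gata6, Prg4 and Alox15, also known from those macrophages, were picked after their values were seen and so describe the cluster without testing it: Gata6 reached 10 TPM in 8 of 21 cells of cluster 2 and 0 of 33 of cluster 1, and the others had medians of 3545 and 3918 TPM in cluster 2. Adjustment for the number of genes at 10 TPM or more, which is larger in cluster 2, covered 2058 genes. These were higher there by at least 1 in the clusters made from the gene set that did not hold them. Between clusters 1 and 2 some of them differed by less. A median of 60.9% (quartiles 29.6 and 85.3%) of their differences between clusters 1 and 2 was left. The part of genes detected in them thus stays open, as does, untested, whether interstitial cells can hold the same programme.

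The values under 10 TPM may come from reads of other cells assigned to a cell, or from low transcription. Across 2773 genes, which are not independent, rho between mean TPM and the share of low cells with a value above 0 was 0.236, between the bounds set in advance for and against the former. Among 207 genes used mostly by 1 cluster, low values were 3.75 percentage points more frequent in the cluster that uses the gene (quartiles -6.35 and 14.3). Cluster 2 used 174 of these genes and cluster 1 used 33. In the median cell of cluster 2, 34.4% of the values above 0 were under 10 TPM, against 45.6% in cluster 1. The test did not adjust for this difference between the clusters. The median of 3.75 points fell on the side set in advance as against low transcription. The genes spread to both sides of that bound, and low transcription was left open for this reason, a choice made after the value was seen. With the former undecided and the latter left open, the explanations were not told apart by these tests.

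Ighm reached 10 TPM in 22 cells of cluster 1 and none of cluster 2, with a median of 1396 TPM in the former. B cells or their RNA in these cells would bring other abundant B cell transcripts, and 0 of the 22 cells had 10 TPM or more of Cd79a, Cd79b, Ms4a1 or Igkc. Transcription of Ighm by these macrophages may be what is left, as a hypothesis; reads of a related sequence were not tested.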
